A study of Rattus norvegicus with 2 samples.

How the data were processed

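Gene expression was measured with 2-colour Agilent microarrays in H4IIE cells, an established rat hepatoma line used as a model of insulin action in liver cells. Per the labels' protocols, cells were grown for 48 h, kept without serum for 24 h and then exposed to 100 nM insulin or to the solvent alone, a final concentration of 0.006% acetic acid, in medium with 4.5 g/L glucose. RNA was taken after 6 h and after 24 h. Per the series' design text, each condition had 3 biological replicates, each of these was hybridised in technical duplicate with the dyes swapped, and the hybridisations of each time followed an A-optimal scheme of their own. Each deposited sample stands for 8 arrays.

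The authors deposited log ratios of insulin over control, 1 value per probe and time, already summarised over the arrays. The column headings of the deposited tables give the direction, exposed over control. They do not name the base of the logarithm. It is taken here as 2, because the submitters' processing notes name limma, an R package that reports its fold changes on that scale, so every statement of a fold rests on this assumption. Background correction, normalisation, the filter on probes, the limma version and the test and threshold for significance are not given in the sources used here. A value table held 8875 probes, of which 8170 had a value at 6 h, 8457 at 24 h and 7752 at both times. The median log ratio was -0.01 at each time, so both columns were centred close to 0. The deposited ratios come without intensities, standard errors or p-values, and the spread between the biological replicates could therefore not be computed.

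The authors also deposited, for each time, a table of the log2 ratios of the probes they called significant. The 6 h table also held 7158 lines without a log ratio, which were left out, and the 24 h table held 0. The values of each such table and of the value table were compared with a tolerance of 1e-06. At 6 h, 257 of 259 listed values were equal in both sources, and at 24 h, 240 of 247. The smallest listed absolute log ratio was 0.75 at each time. In the value table, 259 probes at 6 h and 242 at 24 h reached an absolute log ratio of 0.75, and of these 1 at 6 h and 0 at 24 h were missing from the corresponding significance table. Among the probes of the value table, the listing therefore behaved almost as a size limit alone. Any other criterion applied at that step removed at most that 1 probe from those above the limit. A criterion applied before the value table was made would leave no trace in this comparison.

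Probe identifiers were not paired with genes in the files. None of them (0 matches) occurred in the rat gene table supplied with the data, which is built on assembly GRCr8. Results are therefore given by probe, several probes may measure 1 gene, and no count below is a count of genes. The 23 gene lists and the rule for named genes, both fixed before the data were examined, could not be applied for the same reason and gave no result. In their place the most extreme listed probe in each direction at each time is identified, a choice made after the values were seen. No significance test was fitted here, since there is 1 value per probe and time. The planned test of the difference between times needed standard errors and was not run.

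From these values the following were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Probes in each deposited table were counted by direction. Probes in both tables were counted over the 7752 probes with both values and set beside the number that independent lists of the same sizes would share and beside the range over 10000 random draws. Pearson and Spearman correlations and the share of probes with the same sign were computed across probes. Shares of probes carry exact or Wilson 95% binomial intervals, which cover counting error only and treat probes as independent, which probes of 1 gene are not. For the same reason no p-value across probes is given for the response to insulin. Random re-assignments of direction, used in the closing section, describe these probes only. The calculations were tested on simulated data for 7752 probes: a planted correlation of 0.5 came back as 0.498, and all 100 of the probes planted as changed at both times were found. The planted probes had fixed values beyond the limit used there, without noise, so finding them was certain if the counting was right. The simulation therefore checked the code and not the detection of changes of the size seen here. The precision of every log ratio is limited by the 3 biological replicates per condition, whatever the number of arrays. How the 8 arrays of each time were divided among these replicates was not examined. Alternatives covered the size limit, the use of the value table in place of the significance tables, subtraction of each time's median, the definition of overlap and the set of probes in the correlation.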

Results

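The series profiled the transcriptional response of H4IIE rat hepatoma cells to insulin, the hormone that in liver lowers glucose output and favours lipid and glycogen storage. Its title places the work in a search for endpoints usable in toxicity testing. There were 2 deposited samples, 1 for an exposure of 6 h and 1 for an exposure of 24 h, each a set of insulin-over-control log ratios summarised from 8 arrays. The hybridisations of each time followed a scheme of their own, so the solvent controls of the 2 times were taken as separate. The design text states 3 biological replicates per condition. Their individual values were not analysed here, so none of the values below has a replicate error or n of its own. The calls are the authors' listing as significant, given without a p-value or a stated test, and all probes are given by identifier, without a gene name.

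The first comparison asked how insulin changed transcript levels after 6 h. In the authors' deposited table, 259 probes were listed as changed, 3.17% of the 8170 probes with a value. Of these, 141 were higher with insulin and 118 were lower, so 54.4% of the listed probes were higher (exact 95% interval 48.2 to 60.6%). The median log ratio was 0.89 among the higher probes and -0.91 among the lower ones. The listed changes were mostly moderate in size: 88 probes reached an absolute log ratio of 1, 50 of them higher and 38 lower, while 9 of the higher and 7 of the lower probes reached 1.5. The highest value in the authors' deposited table was 2.22, for probe A_44_P328292, which on a log2 scale is a 4.66-fold higher level with insulin. The lowest was -1.82, for probe A_42_P751562, a 3.52-fold lower level on the same scale. The smallest listed change, at an absolute log ratio of 0.75, corresponds to 1.68-fold.

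Most probes moved little at 6 h. Of all probes with a value, 89.7% had an absolute log ratio under 0.5, and the middle 90 percent of the probes lay between -0.50 and 0.51. The standard deviation across probes was 0.32. It describes the spread over probes, not the error of a probe.

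The second comparison asked the same question after 24 h. In the authors' deposited table, 247 probes were listed as changed, 2.92% of the 8457 probes with a value. The lower probes were in the majority, with 144 lower and 103 higher. The higher probes made up 41.7% of the listed probes (exact 95% interval 35.5 to 48.1%). The median log ratio was 0.88 among the higher probes and -0.97 among the lower ones. An absolute log ratio of 1 was reached by 97 probes, of which 30 were higher and 67 lower. A value of 1.5 was reached by 5 higher and 10 lower probes. Probe A_42_P543774 had the highest value in the authors' deposited table, 2.52, a 5.75-fold higher level on a log2 scale. The same probe was listed at 6 h with 1.70. Probe A_43_P14910 had the lowest value, -2.45, a 5.48-fold lower level on a log2 scale, and was listed at 6 h with -0.86. Across all probes, 91.5% had an absolute log ratio under 0.5 at 24 h and the standard deviation was 0.30. With the median of -0.01 subtracted from the value table, the higher probes were 46.9% of the 254 probes beyond the same limit.

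The third comparison asked whether the response at 6 h carried on to 24 h. Over the 7752 probes with both values, 97 were in both of the authors' deposited tables. Independent lists of these sizes, 258 and 246 probes, would share 8.19, and 10000 random draws shared at most 21. All 97 probes changed in the same direction at both times: 39 were higher at both, against 1.84 for independent lists, and 58 were lower at both, against 2.19. The number listed in opposite directions was 0, where independent lists would give 2.60 probes higher at 6 h and lower at 24 h, and 1.55 the other way. Among the 97 probes, 54 had the larger absolute log ratio at 24 h and 43 at 6 h. Their median absolute log ratio was 0.94 at 6 h and 1.01 at 24 h.

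The remaining listed probes with both values were in the table of 1 time only. These were 161 probes at 6 h, 101 higher and 60 lower, and 149 probes at 24 h, 63 higher and 86 lower. Listing at 1 time only does not show that the response differed between the times, because the difference itself was not tested. Of the 140 probes listed as higher at 6 h and measured at 24 h, 39 were listed again (27.9%, exact 95% interval 20.6 to 36.1%). By the value table, 38 of the 140 reached 0.75 at 24 h, 43 lay between 0.5 and 0.75, 48 between 0 and 0.5, and 11 below 0. Of the 118 listed as lower at 6 h, 58 were listed again (49.2%, interval 39.8 to 58.5%). By the value table, 57 of the 118 reached -0.75 at 24 h, 30 lay between -0.5 and -0.75, 25 between 0 and -0.5, and 6 above 0. In each direction 1 of the probes listed again was under the limit in the value table. At 24 h the median log ratio was 0.56 for the probes higher at 6 h and -0.72 for those lower at 6 h. Read from the later time, 39 of the 102 probes higher at 24 h (38.2%) and 58 of the 144 lower at 24 h (40.3%) had been listed at 6 h. The median 6 h log ratio of these sets was 0.61 and -0.63. No allowance was made for the selection of each set on its value at 1 time, which by itself makes the value at the other time smaller on average.

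**Figure D1:**
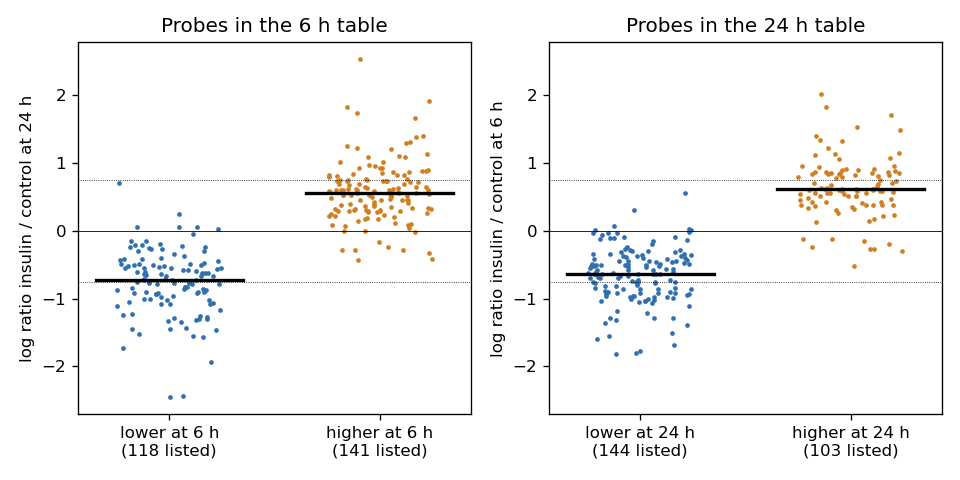
Log ratio (insulin over control, vertical axis, log2 assumed) at the other time for the probes in the authors' 6 h table (left panel) and 24 h table (right panel), split by direction on the horizontal axis, with horizontal scatter added for visibility. Each point is a probe, thick bars are medians and dotted lines mark 0.75 in either direction; the medians are -0.72 and 0.56 on the left and -0.63 and 0.61 on the right.

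Across all 7752 probes the log ratios of both times rose and fell together, with a Pearson r of 0.66 and a Spearman rho of 0.64. These correlations are across probes, which are not independent replicates. The sign was the same at both times for 5662 probes (73.0%, Wilson 95% interval 72.0 to 74.0%). Among the 407 probes listed at either time, r was 0.76 and 92.1% had the same sign. Among the 7345 probes listed at neither time, r was 0.60 and 72.0% had the same sign. The standard deviation across probes at 24 h was 0.96 times that at 6 h. The difference between the times, 24 h minus 6 h, was under 0.5 in size for 94.3% of probes. It reached at least 1 upwards for 26 probes and at least 1 downwards for 33, with extremes of 1.49 and -1.75. Probe A_44_P328292, the highest at 6 h, had 0.73 at 24 h and was not in the authors' 24 h table. Probe A_42_P751562, the lowest at 6 h, had -0.77 at 24 h. These differences were not tested, because the values come without errors.

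**Figure D2:**
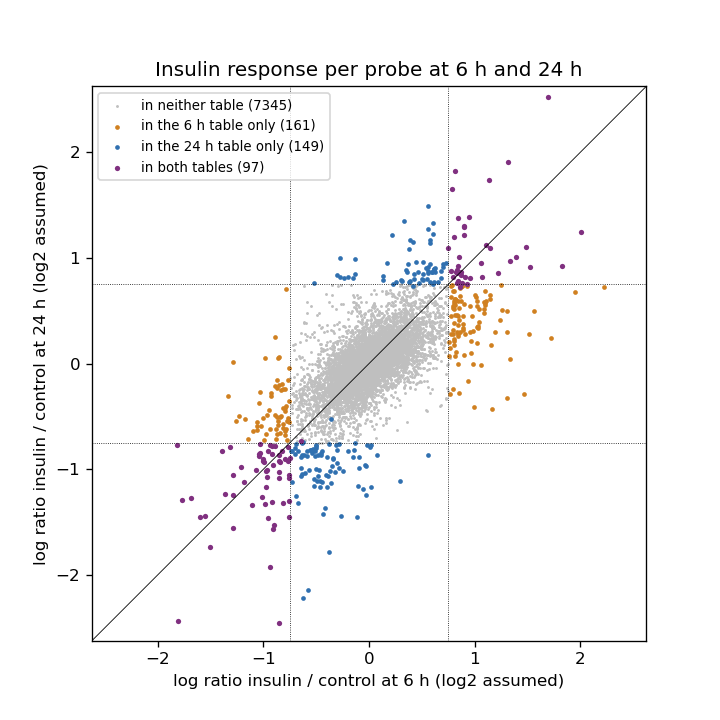
Log ratio (insulin over control, log2 assumed) at 24 h on the vertical axis against 6 h on the horizontal axis, 1 point for each of the 7752 probes with both values, coloured by the authors' table in which the probe is listed. Dotted lines mark 0.75 in either direction and the solid line marks equal values; the 97 probes in both tables lie in the upper right and lower left, with a Pearson r of 0.66 over all points.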

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

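Among the tests in this part, the one on the medians of the value columns, those on probes with a single value and those on the correlation among unlisted probes were chosen after the result was seen.

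Of the 258 probes in the 6 h table that were also measured at 24 h, 17 had a log ratio of opposite sign at 24 h. Of the 246 probes in the 24 h table measured at 6 h, 15 had the opposite sign at 6 h. They drew attention because the effect ran in opposite directions at the 2 times. The difference was not tested, since there is 1 value per probe and time without an error. The opposite value exceeded 0.3 in size for 4 and 3 of these probes and 0.5 for 1 and 2, so most lay close to 0 at the other time.

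Probes lowered at 6 h kept a median of 75.9% of their 6 h log ratio at 24 h, and probes raised at 6 h a median of 56.7%, a difference of 19.2 percentage points. After each of the 118 lowered probes was paired with the raised probe nearest in 6 h size, the difference was 18.6 points. The lowered and raised probes were already close in 6 h size, with median 6 h log ratios of -0.91 and 0.89. The pairing therefore had little to correct and does not decide whether 6 h size plays a part. With each time's median subtracted, the difference was 17.4 points. An equal addition of 0.097 to every 24 h value, against a 24 h median of -0.01, would be needed to remove the difference. Random re-assignment of direction among the 258 probes gave a difference as large in 0.05% of 10000 draws, with the observed assignment counted as 1 further draw. This treats all probes as independent, which probes of 1 gene or of genes regulated together are not. It describes 1 summarised sample per time and not a difference between replicates. Seen from 24 h, lower probes had 63.7% and higher probes 66.4% of their 24 h value at 6 h, a difference of -2.71 points. A candidate explanation, an earlier return of insulin-raised transcripts towards the control level, stays open. Among unlisted probes with a 6 h size of 0.5 to 0.75, lowered probes kept a median of 59.0% and raised probes 55.2%. That difference of 3.83 points lay within the middle 95% of re-assignments (-8.99 to 8.77). The listed raised probes, at 56.7%, were near both values, and the listed lowered probes, at 75.9%, were above them. The unlisted probes were smaller in size at 6 h, so they give no baseline for the listed ones. The values therefore do not show whether the difference lies with the raised or the lowered probes. A few genes with several probes each could also produce the pattern.

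Probes with a value at a single time had a narrower spread of log ratios than the others. The standard deviation was 0.151 for the 418 probes with a 6 h value only and 0.128 for the 705 with a 24 h value only, below the lowest of 10000 random sets of as many probes with both values, 0.267 and 0.259. Dim probes that passed a signal filter at 1 time only, with compressed ratios, may account for the ratio of standard deviations of 0.469 at 6 h. This stays open because the values come without intensities.

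Log ratios of the 2 times also agreed among the 7345 probes in neither table, with r = 0.602, so the listed probes do not carry the correlation. Shifts between the 3 series of probe identifiers do not account for it either, since the lowest r within a series was 0.592. Of the probes in neither table, 72.0% had the same sign. A response to insulin below the size limit at both times stays open and was not tested, as no probe is known to be unaffected by insulin. The dyes were swapped between technical duplicates, per the design text. The 2 times were hybridised on separate arrays in separate schemes, and their controls were taken as separate on that ground. Whether control samples were shared between the times was not tested.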

How the results depend on the processing

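The size limit set the counts. At an absolute log ratio of 1, the counts were 88 at 6 h (50 higher, 38 lower) and 97 at 24 h (30 higher, 67 lower), and the higher share at 24 h was 30.9% against 41.7% in the deposited table. At 0.5 in the value table, a limit chosen after seeing the data, they were 841 (442 higher, 399 lower) and 719 (356 higher, 363 lower), and the higher share at 24 h was 49.5%. The majority of lower probes at 24 h thus widened with the limit and was nearly absent at 0.5. Taken from the value table at the smallest listed log ratio, the counts were 259 at 6 h and 242 at 24 h, and with the medians subtracted 259 and 254. The overlap of 97 became 22 at a limit of 1 at both times and 231 for probes in at least 1 of the tables, those in both included, that reached 0.5 the same way at the other time. It became 334, 6 of them in opposite directions, at 0.5 at both times, which was chosen after seeing the data. The lists themselves changed in size with the limit. The numbers that independent lists of those sizes would share were not computed. Pearson's r of 0.66 became 0.76 among probes in either table and 0.60 in neither, and the same-sign share became 92.1% and 72.0%. Spearman's rho, planned beside Pearson's r but added later to these alternatives, was 0.64. Leaving out the 20 most extreme probes gave r = 0.65. Not run were an adjusted p of 0.01, matching by gene symbol and the gene lists, since the tables give neither p-values nor genes. No replicate could be left out. No paired analysis was possible because each time is 1 summarised sample. Signal over background was not known, so its effect on small ratios could not be assessed.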

Other observations

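The significance tables and the value table differed for a few probes. At 6 h, 2 of 259 listed values differed, and at 24 h, 7 of 247. In each of these cases the listed value was the larger in size, by up to 0.12 at 6 h and 0.29 at 24 h. In the value table, 1 of the 2 and 5 of the 7 lay under the limit of 0.75. In the other direction, 1 probe reached 0.77 at 6 h in the value table and was not listed.

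Listing was unevenly spread over the 3 series of probe identifiers. At 6 h, 4.95% of the 1091 probes beginning A_42 were listed (exact 95% interval 3.74 to 6.41%), 5.50% of the 964 beginning A_43 (4.15 to 7.13%) and 2.49% of the 6115 beginning A_44 (2.11 to 2.91%). At 24 h the shares were 4.71%, 4.60% and 2.35%.

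The tails of the 2 distributions leaned in opposite directions. The skewness across probes was 0.18 at 6 h and -0.28 at 24 h.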
